A study of Mus musculus with 5 samples.

How the data were processed

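RNA was measured in 5 libraries, 3 from control mice and 2 from Rbpj_cKO mice, each from fluorescent cells sorted by flow cytometry from the cortex at postnatal day 2. Per the labels' protocols, cDNA was made and amplified with a SMART-Seq HT kit and libraries with an Ovation Ultralow V2 kit. Neither is stated to keep strand information, and no molecular identifiers are named, so reads are not independent molecules and floors at 0 counts cover counting error only. The submitters' processing notes name HISAT2 2.0.4, StringTie and edgeR and the mouse build GRCm38, also called mm10. Their order, their settings and the annotation release are not given in the sources used here.

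The deposited table gives, per the file headers, a raw read count and an FPKM for each of 34745 Ensembl genes in each library. The FPKM values deposited by the authors equal the count divided by the library's table total and by a factor fixed for each gene. The largest relative deviation of that factor between libraries was 0.000144. Whether the factor equals the gene length was not checked. The tested unit was the raw count. The table names its columns Ctrl and Exp with a number. Columns named Exp were taken as Rbpj_cKO because it is the only group other than control. A total of 18718 genes had a count in some library, and 0 rows named no gene. Gene names and coordinates are those of the table. Of its genes, 98.6% are in GENCODE mouse release 21, where 80.8% of those have identical coordinates. Gene length, GC content, exon overlaps and transcript sequences were taken from that release.

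Totals were 6706962, 6644246 and 6460870 counts in control replicates 1 to 3 and 6946873 and 5671193 in Rbpj_cKO replicates 1 and 2. The mice of a group are separate animals per the labels, though sex transcripts leave it unsettled whether each library held a single animal. No sequencing batch or date is given in the labels, so none could be tested. Between any pair of libraries the counts differed by more than sampling noise (chi-square per degree of freedom from 16.5 to 79.0), so each was kept as its own replicate. With 3 against 2 libraries, an exact permutation test of a value cannot go below p = 0.1, so tests rest on models fitted across all genes.

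The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 with TMM normalization and filterByExpr, which kept 13780 genes, with all 5 libraries, no covariates and Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes are the size of the change divided by the square root of F. The estimated prior had 4.26 degrees of freedom, and the common dispersion was 0.125. CPM values use TMM library sizes. The median log2 fold change over all tested genes was -0.01. Principal components and deviations from the control mean use log2 CPM with a prior count of 2.

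Gene lists were written before the data were examined, from general knowledge of cortical cell types, Notch and other signalling, the cell cycle, stress and other cells that a sort could hold, and 28 had at least 5 tested members. They were tested with camera of limma 3.58.1 with a preset correlation of 0.01 and, as an alternative, with an estimated one, and members were counted past 0.05 over all genes and adjusted over the list alone. The genes named in the text were fixed by a rule before the data were examined. The rule took Rbpj, up to 12 genes in each direction past 0.05 with groups apart and a mean of at least 5 CPM (0 genes), in each list described up to 4 members past 0.05 and otherwise its 2 highest-expressed tested members, and Hes1, Hes5, Olig2, Pdgfra, Ascl1, Mbp, Gfap, Aldh1l1, Sox10 and Egfr. Genes outside it are said to be chosen after their values were seen.

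The simulation drew counts for the 13780 genes from the means, dispersions and depths of these libraries in 5 draws, with 200 genes changed by known folds. In it camera found a raised list of 20 genes in 5 of 5 draws with the preset correlation and in 0 of 5 with an estimated one. Genes were drawn independently of each other, so false calls of the preset setting among correlated genes were not measured. The correlation estimated from the data was 0.0324 for the myelinating, 0.00899 for the committed oligodendrocyte, 0.133 for the endothelial and 0.837 for the mitochondrially encoded list. Alternatives fixed before the data were examined were DESeq2 size factors, no filter on low counts, a mean of at least 5 CPM, the Wald test of DESeq2 1.42.0, limma on log2(FPKM + 1) and log2(FPKM + 0.1) of genes at 1 FPKM or more in at least 2 libraries, leaving out each library, and the replicate number as a block. A robust prior, limma voom with library weights, the fry test and counts over single lists under each alternative were chosen after seeing the data. Where a group is left with 1 library, its spread is assumed to be like that of the other group.

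Near-identical copies were sought with BLAST 2.17.0 among all transcripts of the annotation, at 95% identity or more over at least 200 bases, and a gene was taken as overlapping where it shared at least 5% of the exon bases. Medians in the closing section have 95% intervals from 2000 bootstrap draws over genes, which do not cover the spread between mice. Gene Ontology terms of 15 to 300 tested genes were tested with camera in the same way.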

Results

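Messenger RNA was sequenced in bulk from fluorescent cells sorted from the cortex of mice at postnatal day 2. The cells carried Olig2-Cre, a recombinase expressed in oligodendrocyte-lineage and other glial progenitors, and an H2B-GFP reporter, a histone fused to green fluorescent protein that marks nuclei after recombination. In the Rbpj_cKO group (n = 2 mice per the labels) both alleles of Rbpj, the DNA-binding partner through which Notch receptors act on transcription, were floxed. The labels describe the control group (n = 3 mice per the labels) in 3 ways. These are wild type, Olig2-Cre with the reporter alone, and littermates with 1 floxed Rbpj allele. The number of floxed alleles in controls is thus not settled. Nor is it settled, if wild type means the whole genotype, that controls carried Olig2-Cre and the reporter. Control replicate 1 and Rbpj_cKO replicate 1 each held both Xist (24.2 and 21.2 CPM), from the inactive X chromosome, and the Y-linked Ddx3y (16.4 and 14.2 CPM), both chosen after their values were seen, so it is not settled that n counts single animals. The comparison addressed how the loss of Rbpj changed gene expression in these cells, in a study of Notch signalling in glial development and tumour formation. Each library held 6460870 to 6946873 counts, except Rbpj_cKO replicate 2 with 5671193. That library also stood apart in other respects. Mitochondrially encoded genes took 7.25% of its counts and 1.49 to 3.09% of the others, 14599 genes had a count in it and 15945 to 16307 in the others, and it lay at 109 on the first principal component (55.6% of the variance) while the others lay between -32.1 and -22.3.

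The Rbpj transcript (ENSMUSG00000039191, chromosome 5, 53466152 to 53657362, plus strand, GRCm38) was measured at 23.8, 28.6 and 29.1 CPM in control replicates 1 to 3 and at 26.5 and 24.9 CPM in Rbpj_cKO replicates 1 and 2. The log2 fold change, given throughout as Rbpj_cKO minus control with its standard error, was -0.08 ± 0.25 (edgeR adjusted p = 0.96). The labels do not say which exons were floxed, and a transcript that has lost some exons still adds to a count over the whole gene, so this value does not check the labels. A near-identical copy in the table, Rbpsuh-rs3, held 166 counts over the 5 libraries beside the 866 of Rbpj, and the log2 ratio of the pooled counts of both was -0.18.

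In Rbpj_cKO cells, the gene lists of myelinating and of committed oligodendrocytes were called higher by the list test camera with its preset correlation, and not with an estimated one (adjusted p = 0.108 for both). Mbp, which encodes myelin basic protein, was at 394 ± 82.6 CPM (SD, n = 2) in Rbpj_cKO and 54.9 ± 15.5 CPM (SD, n = 3) in controls. The endothelial, pericyte and erythroid lists were called lower with the preset correlation, and not with an estimated one (adjusted p = 0.152, 0.152 and 0.226). The endothelial claudin Cldn5 was at 10.7 ± 1.43 CPM against 30.8 ± 6.82 CPM, and in the erythroid list 4 of 8 members, all haemoglobin genes, had lower values. The astrocyte and radial glia lists were also called lower, by smaller medians, and not with an estimated correlation (adjusted p = 0.415 and 0.216). Among direct Notch targets the repressor gene Hes5 was at 473 ± 82.7 CPM against 822 ± 151 CPM, while Hes1 was at 65.1 ± 14.1 CPM against 69.9 ± 4.45 CPM.

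**Figure D1:**
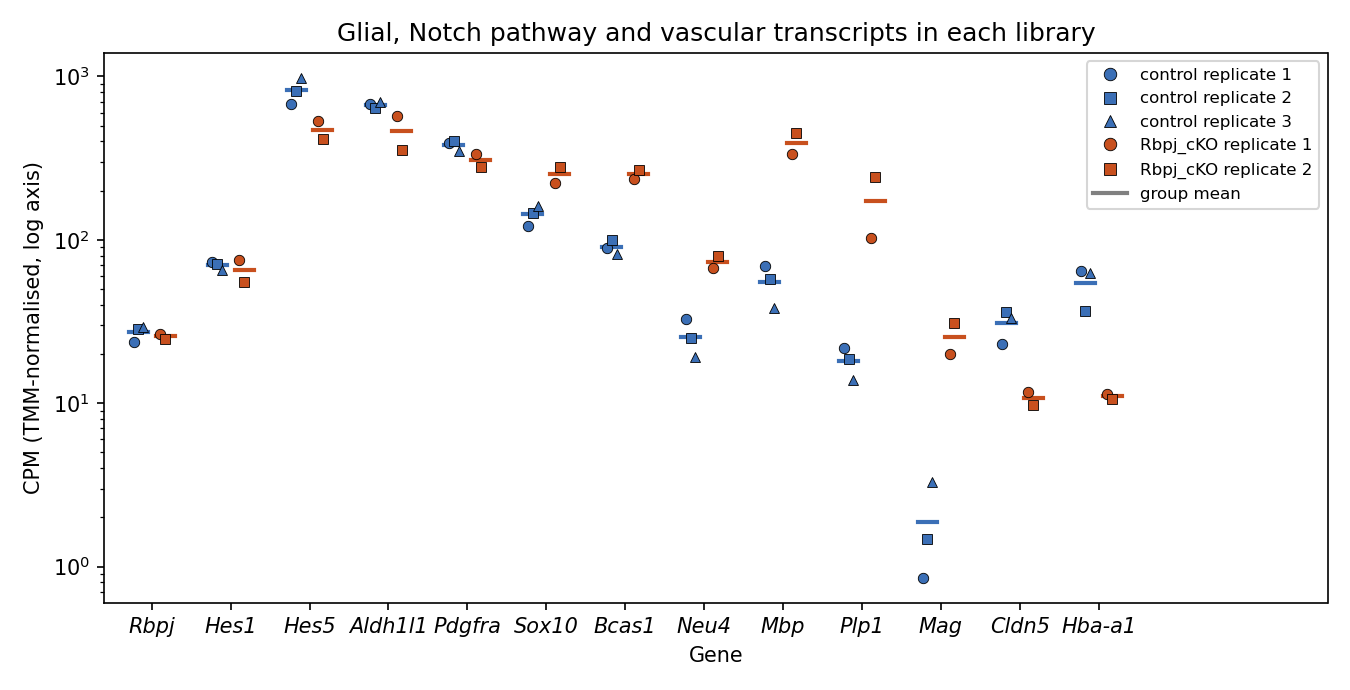
Levels of 13 genes in each library, as TMM-normalised CPM on a logarithmic axis, with each library as a point (blue for control, orange for Rbpj_cKO, symbol by replicate) and the group mean as a bar. Mbp lay between 38.2 and 68.9 CPM in the 3 controls and at 336 and 452 CPM in the 2 Rbpj_cKO libraries, and Rbpj lay between 23.8 and 29.1 CPM in all 5.

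No gene passed an adjusted p of 0.05 over the 13780 genes tested with edgeR (0 higher and 0 lower; smallest adjusted p = 0.113, for Mbp and for the zinc finger gene Zfp422, chosen after its values were seen). At an unadjusted p under 0.05 there were 873 genes, 480 higher and 393 lower. Grouping Rbpj_cKO replicate 2 with control replicates 1, 2 and 3 instead gave 635, 845 and 811 such genes. Of these, 0, 2 and 1 passed an adjusted p of 0.05 in edgeR. The count over all genes thus hardly sets the real grouping apart. DESeq2 called 35 genes higher and 26 lower. Of these 61 genes, edgeR tested 60, and all 60 had an unadjusted edgeR p under 0.05. Both tests used the same counts, so this overlap is no independent support for the calls. The 2 groups did not overlap for 3145 genes, or 22.8% of those tested, where chance gives 20%. On counts simulated from these libraries, edgeR found 9.6% of the genes changed 2-fold and 65% of those changed 4-fold. DESeq2 found 32% and 84.4%. Calls per draw averaged 85.2 in edgeR and 164.2 in DESeq2, of which 9 and 42.6 were false (10.6% and 25.6%). The share of false calls depends on how many genes were changed in the simulation, so it cannot be applied to the 61 DESeq2 calls. An average of 42.6 false calls would be most of those 61. Of 28 gene lists fixed before the data were examined, 5 were higher and 8 lower past 0.05 in camera with its preset correlation between genes of 0.01. With an estimated correlation 0 lists passed (smallest adjusted p = 0.108). Without Rbpj_cKO replicate 1, the library that stood apart was alone in its group and edgeR called 520 genes higher and 553 lower. Without Rbpj_cKO replicate 2 it called 0 higher and 1 lower, and without control replicate 2 it called 1 higher and 0 lower.

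Genes of myelinating oligodendrocytes formed the list with the smallest p. Of 20 tested members, 17 had higher and 3 lower values in Rbpj_cKO, and the median log2 fold change was 0.86 (1.30 without control replicate 2, 0.50 with limma on log2(FPKM + 1)). The list passed camera with the preset correlation (adjusted p = 6.06e-20) but not otherwise (adjusted p = 0.108 with an estimated correlation). Adjusted over the list alone, 9 members rose, 0 fell and 11 did not pass; adjusted over all genes, 0 passed. These 9 were Mbp, Plp1, Mag, Mog, Cnp, Fa2h, Myrf, Cldn11 and Ugt8a, of which all but Mbp and Cnp were chosen after their values were seen. The Mbp change was 2.84 ± 0.27 on the log2 scale (edgeR adjusted p = 0.113; chromosome 18, 82475146 to 82585637, ENSMUSG00000041607). Plp1, the major proteolipid of myelin, changed by 3.25 ± 0.38, from 18.1 ± 3.94 to 172 ± 98.2 CPM (X chromosome, 136822671 to 136839733, ENSMUSG00000031425). Myrf, the transcription factor that switches on myelin genes, was at 1.69 ± 0.49 CPM in controls and at 5.03 and 18.8 CPM in Rbpj_cKO replicates 1 and 2, and its log2 fold change went from 2.80 to 1.57 without replicate 2. Mog, a late myelin glycoprotein, was at 0.14, 0 and 0 CPM in controls and at 5.31 and 6.41 CPM in Rbpj_cKO. The 2 highest-expressed members, Cnp (a myelin enzyme) and Car2 (carbonic anhydrase), went apart, with Cnp at 0.70 ± 0.15 and Car2 at -0.23 ± 0.35. The median deviation of the members from the control mean was 0.80 in Rbpj_cKO replicate 1 and 1.13 in Rbpj_cKO replicate 2, and between -0.16 and 0.12 in the controls.

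Genes of committed and newly formed oligodendrocytes, the stage between precursor and myelinating cell, showed the same direction. Of 26 tested members, 20 were at higher and 6 at lower values, with a median log2 fold change of 0.35 (0.22 with limma on log2(FPKM + 1)). Camera gave an adjusted p = 2.31e-09 with the preset correlation, and an adjusted p = 0.108 with an estimated correlation. Adjusted over the list alone, 8 members rose, 0 fell and 18 did not pass, and 0 passed over all genes. They were Bcas1, Bmp4, Neu4, Lims2, Enpp6, Sirt2, Cyfip2 and Nfasc, of which all but Sirt2 were chosen after their values were seen. Bcas1, a marker of early myelinating cells, went from 90.5 ± 8.85 to 251 ± 22.3 CPM (1.47 ± 0.17, adjusted p = 0.168), and shares 11.7% of its exon bases with Bcas1os1 on the other strand. Enpp6, a phosphodiesterase of newly formed oligodendrocytes, went from 6.78 ± 4.18 to 80.7 ± 57.0 CPM. Gpr17, a receptor of committed precursors and the highest-expressed example, was at 0.13 ± 0.19. Lims2 and Gpr17 lie on opposite strands and share 188 exon bases, and the library kit is not stated to mark strand, so reads from those bases cannot be assigned to either. Both Rbpj_cKO libraries deviated upward, by medians of 0.35 and 0.45.

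The oligodendrocyte precursor list, which shares 12 of its members with other lists, moved less. Of 32 tested members, 21 were at higher and 11 at lower values, with a median of 0.14. It passed camera with the preset correlation (adjusted p = 0.00448) but not with the other setting (adjusted p = 0.401 with an estimated correlation), and not without Rbpj_cKO replicate 2 (median 0.06, adjusted p = 0.113). Adjusted over the list alone, Sox10, Neu4 and Lims2 rose and the other 29 did not pass. This count of 3 went to 1, 0 and 0 without control replicates 1, 2 and 3 and to 5 without Rbpj_cKO replicate 1, and to 0 with the replicate number as a block, where 16 of 32 members were higher and the median was 0.025. The median was 0.049 with limma on log2(FPKM + 1), and the camera call ended with limma on log2(FPKM + 0.1) (median 0.04, adjusted p = 0.0517). Without control replicates 1 and 3 the median was 0.237 and 0.064. Sox10, a transcription factor of the whole oligodendrocyte lineage, was at 252 ± 40.5 CPM against 143 ± 20.4 CPM (0.81 ± 0.19, adjusted p = 0.734). The lineage factors Olig2 (-0.09 ± 0.15) and Olig1 (-0.13 ± 0.17), the precursor receptor Pdgfra (-0.31 ± 0.17) and the endothelin receptor Ednrb (-0.03 ± 0.17) did not pass, nor did the proneural factor Ascl1 (0.48 ± 0.20). Pdgfra was at -0.17 without Rbpj_cKO replicate 2. Olig1 and Ednrb changed sign when some libraries were left out.

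**Figure D2:**
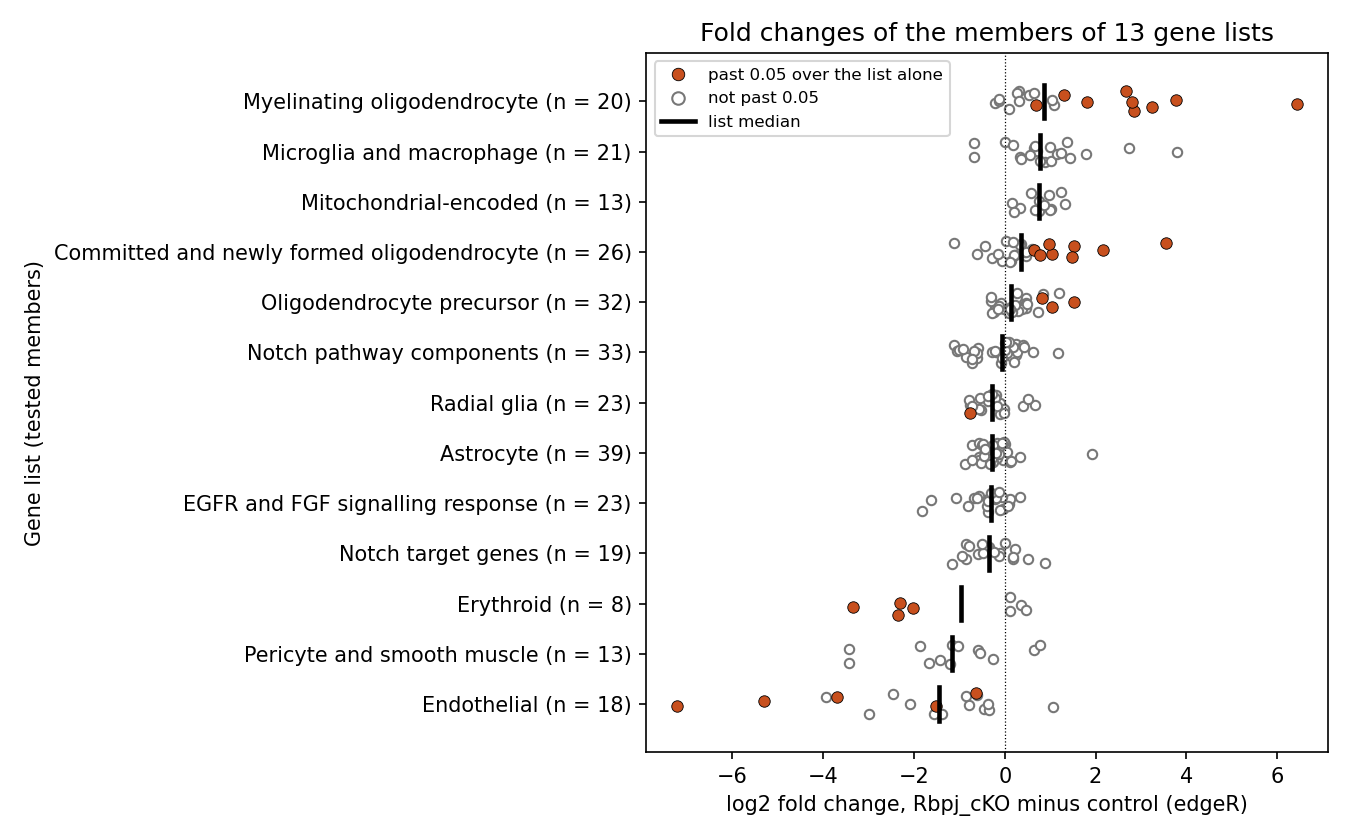
Log2 fold changes (Rbpj_cKO minus control) of the tested members of 13 gene lists, one row per list, with members past 0.05 over the list alone filled, other members open, and the list median as a bar. Medians ran from 0.86 for the myelinating oligodendrocyte list to -1.45 for the endothelial list, and all 4 filled points of the erythroid list are haemoglobin genes.

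Notch target genes, a list that shares 11 of its tested members with other lists, were mostly at lower values. Of 19 tested members 13 were lower and 6 higher, with a median log2 fold change of -0.35, and 0 passed over the list alone or over all genes. Camera did not call the list (adjusted p = 0.0697, and adjusted p = 0.401 with an estimated correlation). Hes5 (chromosome 4, 154960923 to 154962371, ENSMUSG00000048001), a repressor of glial and neuronal differentiation, was lower in 2 of 2 Rbpj_cKO libraries than in every control (-0.80 ± 0.21, adjusted p = 0.751). Gm20421, on the other strand, shares 31.8% of the exon bases of Hes5. Hes1 was at -0.10 ± 0.21 and changed sign without Rbpj_cKO replicate 2. Fabp7, a lipid-binding protein of radial glia, was at 0.52 ± 0.35, with 14453 CPM in Rbpj_cKO replicate 2 and 5673 CPM in replicate 1, and also changed sign without replicate 2. Of the genes chosen after their values were seen, the target Nrarp was at -0.48 ± 0.23 (-0.31 without control replicate 2, -0.28 without Rbpj_cKO replicate 2; Gm38287 on the other strand shares 79.4% of its exon bases), Hey1 at -0.13 ± 0.21 and Myc, a growth regulator, at 0.88 ± 0.27. Notch pathway components, such as ligands, receptors and processing enzymes, went both ways, with 16 of 33 higher, 17 lower and a median of -0.06 (camera adjusted p = 0.271). That median was -0.135 without Rbpj_cKO replicate 1 and -0.003 without replicate 2. The highest-expressed, Dner and the ligand Dll3, were at 0.18 ± 0.20 (0.34 and 0.071 without control replicates 1 and 3) and 0.25 ± 0.17 (0.061 and 0.413 without Rbpj_cKO replicates 1 and 2). The receptor Notch2 and the corepressor Spen, chosen after their values were seen, were at -1.0 ± 0.35 and -1.06 ± 0.38.

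Astrocyte genes were at lower values in 33 of 39 tested members, with a median of -0.29. The list passed camera with the preset correlation (adjusted p = 9.98e-05; adjusted p = 0.415 with an estimated correlation), and 0 members passed over the list alone or over all genes. The median deviation was -0.13 in Rbpj_cKO replicate 1 and -0.45 in the library that stood apart, replicate 2, and the list median was -0.15 without replicate 2 and -0.49 without replicate 1. Aldh1l1, a folate enzyme used as an astrocyte marker, was at 466 ± 156 CPM against 671 ± 28.2 CPM (-0.53 ± 0.22, adjusted p = 0.756), with -0.92 without Rbpj_cKO replicate 1 and -0.22 without replicate 2. Gfap, an intermediate filament protein, was at -0.45 ± 0.31 (-0.14 without control replicate 3, -0.80 and -0.17 without Rbpj_cKO replicates 1 and 2), and the protease inhibitor Cst3 and the glutamate transporter Slc1a3 were at -0.30 ± 0.17 (-0.19 without control replicate 3) and -0.21 ± 0.23, the latter changing sign without Rbpj_cKO replicate 2. S100b, a calcium-binding protein found in astrocytes and in myelinating oligodendrocytes and chosen after its values were seen, went the other way (1.92 ± 0.47), at 19.0 and 59.8 CPM in Rbpj_cKO against 9.44 to 11.8 CPM in controls, and at 0.88 without Rbpj_cKO replicate 2.

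Radial glia genes, the list of neural stem and progenitor cells, were at lower values in 20 of 23 tested members (median -0.28). Other lists share 12 of these 23 members, so the lower lists are not separate observations. The camera adjusted p was 0.0039 with the preset correlation, and the list did not pass otherwise (adjusted p = 0.216 with an estimated correlation). The list median was -0.17 without Rbpj_cKO replicate 2. Adjusted over the list alone, Vim, the intermediate filament vimentin, chosen after its values were seen, fell by 0.77 on the log2 scale, from 333 ± 30.8 to 195 ± 5.61 CPM, and 22 members did not pass. This call was not made without any one of the controls, without Rbpj_cKO replicate 2, with the replicate number as a block, with limma on FPKM at either pseudocount or with voom weights (0 members each). Without Rbpj_cKO replicate 1 there were 9 members past 0.05, and 3 with no filter on low counts or with DESeq2. The log2 fold change of Vim lay between -0.843 and -0.72 when each library was left out in turn. Mfge8, a secreted glycoprotein also chosen after its values were seen, was at -0.69 ± 0.21. Genes that respond to EGFR and FGF signalling were at lower values in 18 of 23 members (median -0.31; camera adjusted p = 0.00303; adjusted p = 0.474 with an estimated correlation), and 0 passed over the list alone. Without Rbpj_cKO replicate 2 their median was -0.17 and the camera call ended (adjusted p = 0.181), and the median was -0.20 and -0.11 without control replicates 2 and 3 and -0.49 without Rbpj_cKO replicate 1, and -0.15 with the replicate number as a block. Egfr itself was at -0.36 ± 0.19 (-0.55 and -0.19 without Rbpj_cKO replicates 1 and 2), and the highest-expressed members, Etv5 and Dusp6, lay near 0 at 0.06 ± 0.17 and -0.03 ± 0.21. Etv4 and Fgfbp3, chosen after their values were seen, were at -1.07 ± 0.29 (-1.61 and -0.68 without Rbpj_cKO replicates 1 and 2) and -0.67 ± 0.19.

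Markers of other cell types also differed between the groups. Endothelial genes were at lower values in 17 of 18 tested members, with a median of -1.45 (camera adjusted p = 3.31e-12; adjusted p = 0.152 with an estimated correlation). Adjusted over the list alone 5 fell, 0 rose and 13 did not pass, and 0 passed over all genes. These were Cldn5, Pecam1, Emcn, Esam and Mfsd2a, of which all but Mfsd2a were chosen after their values were seen. Cldn5 changed by -1.52 ± 0.33 and the lipid transporter Mfsd2a by -0.64 ± 0.19. The adhesion protein Pecam1 was at 2.34 to 5.31 CPM in controls and at 0.14 and 0 CPM in Rbpj_cKO. Emcn, an endothelial sialoprotein, was at 2.36 to 3.27 CPM in controls and had 0 counts in both Rbpj_cKO libraries, at least 11.6-fold lower against a floor of 3 counts over the group, and with Emcn at that bound the list median was the same. Bsg, the highest-expressed member, was at -0.34 ± 0.17. The count of 5 went to 1, 0 and 0 without control replicates 1, 2 and 3, and to 9 without Rbpj_cKO replicate 1. The list median went to -0.94 without control replicate 3 and to -4.04 without Rbpj_cKO replicate 1, and it was -0.74 over the members with a mean of at least 5 CPM and -0.55 and -0.69 with limma on log2(FPKM + 1) and log2(FPKM + 0.1). Pericyte and smooth muscle genes were at lower values in 11 of 13 members (median -1.16; camera adjusted p = 0.000111; adjusted p = 0.152 with an estimated correlation), with 0 past 0.05 over the list alone. The median was -2.37 without Rbpj_cKO replicate 1. The contractile protein Myl9 and the receptor Notch3, its highest-expressed examples, were at -1.16 ± 0.54 and -0.59 ± 0.34, and Myl9, at 16.6 and 4.47 CPM in Rbpj_cKO replicates 1 and 2, was at -2.42 without replicate 1 and -0.52 without replicate 2.

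In the erythroid list, which had a median of -0.96, 4 of 8 tested members fell when adjusted over the list alone and 4 did not pass (camera adjusted p = 8.1e-05; adjusted p = 0.226 with an estimated correlation; adjusted p = 0.106 without Rbpj_cKO replicate 1). The list median was -2.27 without Rbpj_cKO replicate 2, -1.55 without replicate 1, -1.56 with no filter on low counts, and -1.87 and -2.13 with limma on log2(FPKM + 1) and log2(FPKM + 0.1). All 4 that fell were haemoglobin genes, chosen after their values were seen. Hba-a1 was at 11 ± 0.45 CPM against 54.8 ± 15.5 CPM (-2.31 ± 0.33, adjusted p = 0.35), Hba-a2 at -2.35 ± 0.57, Hbb-bs at -2.03 ± 0.48 and Hbb-bt at -3.34 ± 0.71. Hba-a1 and Hba-a2 are near-identical, as are Hbb-bs and Hbb-bt, so the division of counts within each pair is uncertain. The highest-expressed members, Bpgm and Snca, which are also active in neurons, were at 0.12 ± 0.16 and 0.12 ± 0.22.

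Microglia and macrophage genes went the other way, with 19 of 21 members at higher values (median 0.78; camera adjusted p = 7.29e-05; adjusted p = 0.458 with an estimated correlation) and 0 past 0.05 over the list alone. The median deviation was -0.18, -0.32 and 0.60 in control replicates 1 to 3 and 0.62 and 1.15 in Rbpj_cKO replicates 1 and 2, so control replicate 3 was near Rbpj_cKO replicate 1. The list median was 1.33 without control replicate 3, 1.22 without Rbpj_cKO replicate 1 and 1.38 with the replicate number as a block. Only 6 of the 21 had a mean over 5 CPM. The highest-expressed, Hexb and Lyz2, were at 0.01 ± 0.25 and 0.66 ± 0.59, and both changed sign in some of the alternatives. Cx3cr1, Csf1r and P2ry12, receptors of microglia chosen after their values were seen, were at 3.79 ± 1.23, 1.01 ± 0.36 and 1.23 ± 0.49, with Cx3cr1 at 6.45 without control replicate 3 and Csf1r at 0.62 without Rbpj_cKO replicate 2. Csf1r shares 15.1% of its exon bases with Hmgxb3, and Hexb 32.3% with Gfm2, on the other strand. Mitochondrially encoded genes had higher values for 13 of 13 members (median 0.75; camera adjusted p = 0.00147; adjusted p = 0.533 with an estimated correlation), with 0 past 0.05 over the list alone. The direction came from the library that stood apart. The median deviation was 1.48 in Rbpj_cKO replicate 2 and -0.48 in replicate 1, and without replicate 2 the list was called lower (median -0.53, adjusted p = 0.00529), while without replicate 1 the median was 1.32. The counts of its highest-expressed members, mt-Co3 (1.24 ± 0.69) and mt-Atp6 (0.96 ± 0.71), are uncertain, since each has a near-identical nuclear copy in the table, and mt-Atp6 was at 0.52 and 2.14 without control replicates 1 and 2.

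Of the other 15 lists, camera with the preset correlation called 2. Meningeal fibroblast genes (median -0.38; camera adjusted p = 0.0484; adjusted p = 0.458 with an estimated correlation) and immediate early genes induced by tissue dissociation (median -0.10; camera adjusted p = 0.0484; adjusted p = 0.42 with an estimated correlation) were the 2. The meningeal call ended without control replicates 2 and 3 (medians -0.28 and -0.19, adjusted p = 0.101 and 0.0823), without Rbpj_cKO replicate 2 (-0.06, adjusted p = 0.406) and with the replicate number as a block (-0.24, adjusted p = 0.0841), and its median was -0.98 without Rbpj_cKO replicate 1 and -0.585 and -0.593 with limma on log2(FPKM + 1) and log2(FPKM + 0.1). The immediate early call ended without control replicate 2 (-0.15, adjusted p = 0.185), without Rbpj_cKO replicates 1 and 2 (-0.17 and -0.35, adjusted p = 0.2 and 0.0723) and at a mean of at least 5 CPM (adjusted p = 0.109). Camera did not call cholesterol synthesis (median -0.21, adjusted p = 0.0675), GABAergic neurons (0.18, adjusted p = 0.0764), pan-neuronal genes (0.04, adjusted p = 0.0793), the interferon response (-0.38, adjusted p = 0.209), the Shh pathway (-0.17, adjusted p = 0.321), the G2M phase of the cell cycle (0.03, adjusted p = 0.353), intermediate neuronal progenitors (0.25, adjusted p = 0.375), glioma-associated receptors and regulators (-0.20, adjusted p = 0.379), the S phase (0.01, adjusted p = 0.537), apoptosis and the p53 response (-0.06, adjusted p = 0.588), the BMP and TGF-beta response (-0.25, adjusted p = 0.665), proneural factors (-0.03, adjusted p = 0.941) or glutamatergic neurons (0.02, adjusted p = 0.994). With 1 library left out, camera called pan-neuronal genes higher without control replicate 1 (0.32, adjusted p = 0.000408) and without Rbpj_cKO replicate 1 (0.23, adjusted p = 0.0235), GABAergic neurons higher without control replicate 1 (0.17, adjusted p = 0.035), the S phase higher without Rbpj_cKO replicate 2 (0.17, adjusted p = 0.011) and cholesterol synthesis lower without Rbpj_cKO replicate 1 (-0.35, adjusted p = 0.0302). Without Rbpj_cKO replicate 2 the GABAergic median was -0.11 and the cholesterol median was -0.088. The interferon median was -0.612 and -0.157 without control replicates 1 and 3. For intermediate neuronal progenitors the mean log2 fold change was -0.16 where the median was positive, and for proneural factors and glutamatergic neurons the camera statistic had the sign opposite to the median. Within these lists 1 member each rose when adjusted over the list alone in the GABAergic list (Calb2, the calcium-binding protein calretinin, 1.76 ± 0.24) and in the BMP list (Bmp4, a secreted morphogen, 2.15 ± 0.36), both chosen after their values were seen. The fry test, chosen after the data were seen, asks whether the members of a list moved one way on balance, and it called the myelinating and the committed oligodendrocyte lists (adjusted p = 0.0406 for both) and 0 others. Its form for changes in either direction within a list called 6, the same 2 and the endothelial (adjusted p = 0.0241), GABAergic (adjusted p = 0.0241), erythroid (adjusted p = 0.044) and pericyte (adjusted p = 0.044) lists.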

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

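The robust prior, the voom weights, the fry test and the counts over single lists under each alternative were chosen only after the result was seen.

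Camera was not run with the DESeq2 Wald test, the robust prior or the voom weights. Over the other alternative fits, the camera direction of 17 of 28 lists never changed, and for 16 the median kept its sign as well. Over all alternatives, the sign of 58 of 73 named genes never changed. Members past 0.05 over the list alone ranged from 6 to 10 in the myelinating and from 6 to 8 in the committed oligodendrocyte list. Genes called higher and lower numbered 3 (Bcas1, Mbp, Plp1) and 1 (Zfp422) with no filter on low counts, 35 and 26 with the DESeq2 Wald test, and 1 (Mbp) and 1 (Zfp422) with voom weights. Lists called higher and lower numbered 0 and 0 with an estimated correlation and 2 and 0 with fry. Endothelial members past 0.05 over the list alone numbered 3 at a mean of at least 5 CPM, 3 and 3 with limma on log2(FPKM + 1) and log2(FPKM + 0.1), 0 with voom weights and 0 with the replicate number as a block, and erythroid members 1 with voom weights. Fewer endothelial members were tested at 5 CPM (10) and with limma on FPKM (8) than in the main test (18), and beyond that the cause was not tested.

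With no filter the glutamatergic median was 0.016 with the camera direction reversed. Etv5 was at -0.019 and -0.02 and Hexb at -0.053 and -0.055 with limma on log2(FPKM + 1) and log2(FPKM + 0.1). With the replicate number as a block, edgeR called 0 genes higher and 0 lower (501 at an unadjusted p under 0.05), and Dusp6 was at 0.077. Correlations of changes between libraries of the same replicate number were 0.0212 and 0.0544. With the Rbpj_cKO libraries swapped they were -0.0212 and -0.0544, exact mirror images, so this check could not show or exclude pairing. Sex transcripts left pairing open. Both libraries of replicate 1 held Xist and Ddx3y. The other numbered pair held Ddx3y (60.5 and 145 CPM) with little or no Xist (0.738 and 0 CPM). The unpaired test was kept as the main test. The cause of the reversals of the glutamatergic list, Etv5, Hexb and Dusp6 was not tested. A pseudocount of 1 shrinks the folds of genes of few counts by construction, and with limma on log2(FPKM + 1) Cx3cr1 was at 0.976, P2ry12 at 0.511, Notch2 at -0.597 and Spen at -0.495.

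Leaving out each library in turn, genes called higher ranged from 0 to 520 and lower from 0 to 553. Both highest counts came without Rbpj_cKO replicate 1. The other calls were Sla2 higher without control replicate 2 and Zfp422 lower without Rbpj_cKO replicate 2. Endothelial members past 0.05 ranged from 0 to 9. Lists called ranged from 4 to 7 higher and from 6 to 8 lower. Lists that reversed in median or camera direction ranged from -0.21 to 0.097 (apoptosis), -0.447 to -0.083 (BMP), -0.085 to 0.081 (G2M phase), -0.174 to 0.166 (S phase), -0.349 to -0.007 (glioma-associated), -0.132 to 0.112 (glutamatergic), -0.115 to 0.305 (GABAergic, in median alone), 0.135 to 0.371 (intermediate progenitor), -0.534 to 1.316 (mitochondrial), -0.105 to 0.319 (pan-neuronal), -0.107 to 0.12 (proneural) and -0.404 to -0.014 (Shh). Genes that reversed ranged from -0.002 to 0.223 (Bpgm), -0.941 to 0.248 (Car2), -0.26 to 0.16 (Dusp6), -0.125 to 0.074 (Ednrb), -0.09 to 0.193 (Etv5), -0.308 to 1.029 (Fabp7), -0.04 to 0.279 (Gpr17), -0.352 to 0.104 (Hes1), -0.101 to 0.146 (Hexb), -0.311 to 0.024 (Hey1), -0.067 to 1.648 (Hmgb2), -0.271 to 1.222 (Lyz2), -0.317 to 0.036 (Olig1), -0.64 to 0.117 (Slc1a3) and -0.629 to 2.021 (mt-Co3). The cause was not tested beyond there being fewer samples. Depth limits genes of a few counts, such as Mog and Emcn.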

Other observations

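All tests here were chosen only after the result was seen, except the length and GC corrections and the count over splits, and some of their bounds were set or redefined after values were known, so the values carry more than whether a bound was met.

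Of 3600 Gene Ontology terms, camera with the preset correlation called 1 higher, substantia nigra development (median log2 fold change 0.14, adjusted p = 0.00432, adjusted p = 0.999 with an estimated correlation), led by Mbp, Plp1, Mag, Sirt2 and Cnp, and 0 lower. Xist, the transcript of the inactive X chromosome, was at 24.2, 0.738 and 36.3 CPM in control replicates 1 to 3 and at 21.2 and 0 CPM in Rbpj_cKO replicates 1 and 2. The Y-linked Ddx3y was at 16.4, 60.5 and 0 CPM and at 14.2 and 145 CPM. Control replicate 1 and Rbpj_cKO replicate 1 held both transcripts, and the labels do not say whether cells of several pups were pooled. The sex composition thus differed between libraries of both groups, and it was not in the model. Xist and Ddx3y were chosen after their values were seen.

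The 2 oligodendrocyte lists had a joint median of 0.473 in Rbpj_cKO against control. It was 0.595 without Rbpj_cKO replicate 1 and at 0.547 without replicate 2, and a correction for transcript length and GC content left it at 0.542, which argues against one library or that bias as the whole source. Fewer vascular cells in the sort would raise all glial transcripts alike. The median of the oligodendrocyte lists exceeded that of the astrocyte list, itself at -0.29, by 0.761 (95% interval 0.523 to 1.13). Both directions were known when this contrast was set, so the interval restates them and is no separate test. The real split gave 20 of 46 members at an unadjusted p under 0.05 and the highest other split 11 (1 of 10 splits as large). The 2 lists were taken up because they were higher in the real split, which favours it in this count. Over all genes it gave 873 and the highest other split 845. Also, 10 splits are too few for a share under 0.05. The Rbpj genotype, sex, litter, pup stage and the control genotype stay open and untested as explanations. The count of the Rbpj transcript itself was at -0.08.

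The 35 endothelial, pericyte and haemoglobin genes had a median of -1.44, with 32 lower and 3 higher (Abcb1a, Zic1 and Des, chosen after their values were seen), and 9 passed 0.05 over their list alone and 0 over all genes. It was -2.26 without Rbpj_cKO replicate 1 and -1.369 without replicate 2, and -1.452 after the length and GC correction, which argues against one library or that bias as the whole source. A lower purity of all control sorts would lower microglia genes too. The median of microglia genes exceeded that of endothelial genes by 2.227 (95% interval 1.35 to 3.51). Both directions were known when this contrast was set, so the interval restates them and is no separate test. Control replicate 3 was also near Rbpj_cKO replicate 1 in microglia genes (median deviations 0.60 and 0.62). By library, haemoglobin genes of at least 5 CPM in controls were at -2.39 and -2.23 and vascular genes at -0.59 and -1.49 in Rbpj_cKO replicates 1 and 2. For the vascular genes, fewer such cells carried through the fluorescence sort, a vessel change and Cre activity in vascular cells cannot be told apart. For the haemoglobin genes, fewer blood cells carried through and a change in the vessels cannot be told apart either. Cre activity was not tested for them. The share of genes of at least 5 CPM in controls below the control mean in both Rbpj_cKO libraries was 90.5% (19 of 21). It pools both sets and restates the pattern, so it cannot separate these causes.

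The 30 genes of smallest p in no list, chosen after their values were seen, included Zfp422 (210, 217 and 231 CPM in controls, 28.8 and 13.6 CPM in Rbpj_cKO) and Hmgn2 (-3.07). A near-identical copy was found for 26.7% of them and for 10.7% of expression-matched genes (one-sided permutation p = 0.0097). Of the 17 with a copy or an overlapping gene, 10 stayed at 0.75 or more of their pooled log2 ratio when summed with it (Zfp422 went from -3.28 to -3.21), 1 lay between 0.5 and 0.75 (Hmgn2, -3.03 to -2.18), 3 fell below 0.5 (Eno1, Entpd2 and Zfp708), and 3 had no partner counts in the table. Summing with a partner of many counts can lower the ratio even where no reads were divided. Entpd2 went from -1.21 to -0.15 with Npdc1, which held 8054 counts, so its fall cannot decide this. Division of reads may account for a few, such as Eno1 (0.79 to 0.12), but for most it was not shown. Reads left uncounted because they match several places cannot be seen in the table. The other 13 had neither a copy nor an overlapping gene, a count known before its bound was set. Of the 30, 0 lay within 20 Mb of Rbpj, which argues against a haplotype flanking Rbpj as the source of these genes. The flanks of the Olig2-Cre and reporter loci were not checked. What separates Entpd2 and the genes not named as falling below 0.5 stays open.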
